A study of Homo sapiens with 8 samples.

How the data were processed

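RNA bound to chromosomes was studied in HEK293T, an established human embryonic kidney cell line, in its parental form (wild type) and with METTL3 knocked out. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. Per the labels' protocols, chromosome-associated RNA was freed of DNA and ribosomal RNA, part of it was immunoprecipitated with an m6A antibody kit (IP), and stranded libraries were made from IP and input. The 8 samples form 4 groups of 2 replicates, namely wild-type input, wild-type IP, knockout input and knockout IP. The series design text also names a HAT1 knockdown, which is not analysed here.

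The submitters' processing notes name HISAT2 2.2.1, SAMtools 1.15.1, MACS2 2.2.7.1 and the human build hg38, without the order or settings of each step. The values used here come from 2 deposited peak lists, 1 per genotype, in the layout MACS2 writes. Each list gives for every peak its position, strand, a score, a fold enrichment, 2 significance values and a summit. The deposited score column of each list is a display value and was not used. The fold column holds a linear ratio of IP over local input at the summit as the authors' peak caller gave it. The −log10 columns hold the deposited −log10 of the p-value and of the q-value. No peak had a −log10 q below 2.01 in wild type or 2.02 in the knockout, and the threshold itself is not given in the sources used here. Whether replicates were pooled before or after calling is also not given there. Each list carries both strands, and no peak overlapped another of its own list on the same strand. Neither list carries values per replicate. No spread between replicates, no left-out replicate and no test of genotype across replicates could therefore be computed, and every p-value below describes the peaks or genes of these 2 lists, which are not replicates.

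Overlaps, gene assignment and tests were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9. A peak was called shared if a peak of the other list overlapped it by at least 1 bp on the same strand. Shares have 95% Clopper-Pearson intervals, which cover counting error only. Chance overlap came from 100 shuffles of the other list's peaks, within merged gene bodies of the same chromosome or within the same merged gene body. Folds were ranked and tested within a list, by 2-sided permutation tests with 100000 resamples. As an alternative, peaks of each list were also counted above the median fold of both lists pooled, although the ratio of IP to input depth, and with it the scale of the folds, differs between the lists. Shares were compared by 2-sided Fisher's exact tests. Peaks were assigned to every protein-coding or long noncoding gene body they overlapped, in the RefSeq table of GRCh38.p14, the build of the lists. That table holds 59702 genes and gives bounds without strand, exons or sequence. A peak was therefore assigned regardless of strand, and a gene can be credited with peaks of a transcript on the opposite strand. Where the text says that a peak lies opposite to a gene, the strand of the gene is background knowledge. The 5′ end of a gene was taken as the bound that is upstream on the peak's own strand, and a window of 500 bp on either side was used. The planned share of peaks over exons, the planned density of the m6A motif and every alternative built on exons were not run.

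The 15 gene lists, the overlap rule, the tests of the shares, the folds and the gene ends, and the rule for naming genes were fixed before the data were examined. Under that rule the text names the 10 wild-type-only, 10 shared and 10 knockout-only peaks of highest fold, 1 per gene. It also names METTL3, HAT1, members of the lists of writers, readers and erasers, histone acetyltransferases and long noncoding RNAs with a peak, and up to 4 members of each other list. The rule asked for peaks over an exon, and was applied instead to peaks lying in the body of exactly 1 protein-coding or long noncoding gene. Genes singled out by other counts were chosen after their values were seen. A gene that the rule would name among the other lists is not reported here. Mitochondrially encoded genes were taken as all genes on the mitochondrial chromosome. The lists were tested by gene with Benjamini-Hochberg adjustment over the 15 lists. The comparison within strata of 1, 2 and 3 or more wild-type peaks, planned as a Mantel-Haenszel test, was run as a permutation test within the strata. Counting by peak, and counting by peak against gene peaks of similar read support, were added after seeing the data, as was a test by gene in which a knockout peak had to lie on a strand with a wild-type peak, so the lists were tested in 6 ways in all.

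Whole reads behind each peak were recovered after seeing the data. MACS2's fold is (IP pileup + 1) / (local input + 1) and its p-value is a Poisson tail, so each pair of fold and p gives the IP reads and the local input at the summit, up to the scale of the libraries. A whole number of reads was found for 99.8% of wild-type and 98.4% of knockout peaks. The tolerance was 0.02 of a read at the lowest and widened with the number of reads, so it was loosest at the highest summits. On 5000 simulated peaks the procedure solved 99.9%, and all solved ones were right. When simulated folds were moved by up to 3% it solved 7.24%. The number of reads over a summit exceeded 200 at 198 wild-type and 302 knockout peaks. That is more than 200-bp fragments on 1 strand allow without repeated start positions, so duplicate reads were counted and reads are not independent molecules. The fragment length of 200 bp is itself inferred from the values.

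Also added after seeing the data were a Fisher's exact test per gene of its number of peaks in each list against all other peaks, with Benjamini-Hochberg adjustment over 12202 genes, the same test per chromosome over 23 chromosomes, and the correlation of chromosome peak ratios with local input. Peaks of 1 gene can come from the same transcript and are not independent, so these p-values are too small by an unknown amount. In data simulated for genes with at least 15 peaks, the gene test recovered 22% of genes changed by 4-fold in odds and 79% of those changed by 16-fold, and called 0 of 11999 unchanged genes. The simulation drew the peaks of a gene independently, so it does not measure false calls among dependent peaks. Other settings chosen beforehand were a reciprocal overlap of 50%, the 50% of peaks with the highest fold, equal numbers of strongest peaks, sharing within 500 bp, merged peaks, windows of 200 and 1000 bp, and a stricter fold.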

Results

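The data comprised m6A peaks in chromosome-associated RNA of HEK293T cells with and without METTL3. The wild-type list held 29084 peaks and the knockout list 23937, each standing for 2 IP and 2 input libraries. Total reads per library are not given in the files. The IP depth recovered from the peak values was higher in the knockout than in wild type, by 1.17-fold on the plus strand and 1.20-fold on the minus strand. The recovered input depth was 0.923 and 0.918 of wild type. A wild-type summit had a median of 24 IP reads (quartiles 15 and 42) and a knockout summit 31 (19 and 54). In the fold, each IP read was scaled by 0.607 and 0.572 in wild type and 0.479 and 0.438 in the knockout (plus and minus strands). These medians of unscaled reads are therefore not on the same scale. As neither list holds values per replicate, all differences below lack a replicate check, and the overlap that replicates of 1 genotype would reach is not known.

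The targeted gene was examined first. METTL3, on chromosome 14 from 21498138 to 21511340 (GRCh38), carried 2 wild-type peaks, at 21503361 to 21503569 and 21509944 to 21510143 on the minus strand, with folds over input of 4.83 and 4.91. The knockout list had 0 peaks in METTL3. HAT1, the histone acetyltransferase named in the study's title, had 2 wild-type peaks on chromosome 2 with folds of 7.02 and 6.90. It had 3 knockout peaks with folds of 14.2, 5.82 and 12.0, and no HAT1 peak was shared. The 2 METTL3 peaks rested on 32 and 24 IP reads. Of all genes with 2 wild-type peaks, 34.5% had no knockout peak. Which part of METTL3 was deleted is not given in the sources used here, so its peaks are a weak check of the labels.

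The first comparison asked which peaks of each list had a peak at the same place in the other list. Lost and kept below mean only that a wild-type peak had no such partner or had one. Whether peaks of either list are marks made by METTL3 was not tested. The median fold was 7.29 in wild type and 7.06 in the knockout, on scales that differ. At 5393 shared pairs, log2 IP over local input was higher in the knockout by a median of 0.088 (quartiles −0.637 and 0.813). The knockout list was 17.7% shorter, with 82.3 peaks for every 100 in wild type. Peaks at PCMTD1, DMXL1, PARD3, TOP1 and EED were among the strongest that both lists held, of those in the body of exactly 1 gene. Of the wild-type peaks, 79.6% (95% interval 79.1 to 80.0) had no knockout peak at the same place. The lack of a partner was not one-sided, since 75.2% (74.6 to 75.7) of knockout peaks had no wild-type peak. Peaks at MARK1, SUV39H2 and CHD2 led those found in the knockout list alone and in the body of exactly 1 gene.

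The lists nevertheless met far more often than chance placed them. Among wild-type peaks 5947 (20.4%) were shared, against a mean of 0.324% and a maximum of 0.395% in 100 shuffles over gene bodies of the same chromosome. Knockout peaks were also moved only within their own merged gene body, which can join overlapping genes of either strand. There the observed share in gene bodies was 21.1% against a mean of 1.45% and a maximum of 1.63%. Overlap depended on strand, and 20 wild-type peaks met a knockout peak on the opposite strand. On the plus strand 22.7% of wild-type peaks were shared and on the minus strand 17.9%. The knockout had 85.6 plus-strand and 78.5 minus-strand peaks per 100 of wild type, fewer on both strands.

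Sharing rose with read support in both lists. The classes below are of unscaled reads, which weighed less in the knockout call. The same class is therefore not the same support in both lists. It was 5.53% at wild-type summits of up to 15 IP reads and 69.3% (66.7 to 71.7) above 100 reads, where 937 of 1353 peaks were shared. In the knockout list the same classes gave 5.69% and 69.9% (67.8 to 72.0). The share without a partner thus fell to 46.5% of wild-type and 41.4% of knockout peaks when only the 10% of each list with the highest −log10 q was asked, a choice made after seeing the data.

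**Figure D1:**
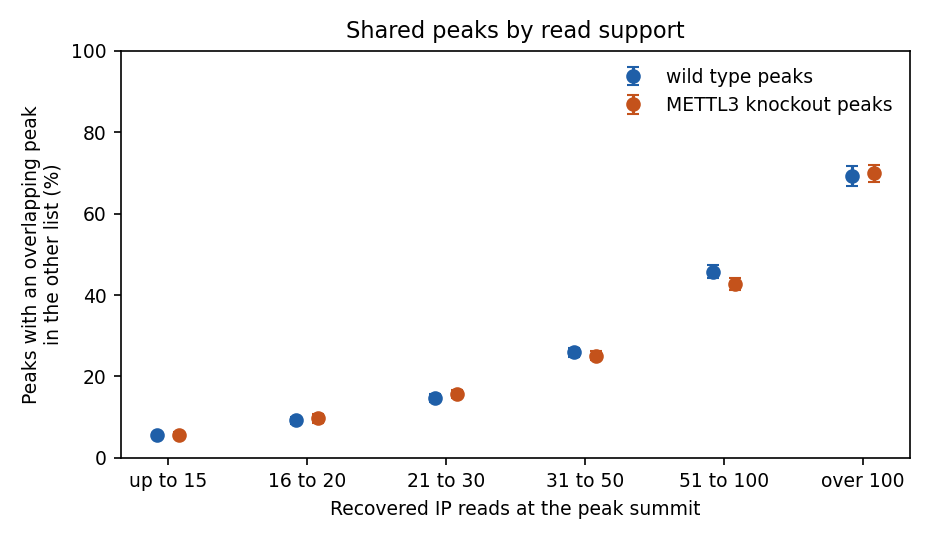
Percent of peaks with an overlapping peak in the other list (vertical axis) by the number of recovered IP reads at the summit (horizontal axis), for wild-type and METTL3 knockout peaks, with 95% Clopper-Pearson intervals. Shared peaks rise from 5.53% to 69.3% in wild type and from 5.69% to 69.9% in the knockout.

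Among wild-type-only peaks in the body of exactly 1 gene, taken 1 per gene, the strongest lay in ADGRB3, DEDD, NBPF20 and RAPGEF4. ADGRB3, an adhesion G protein-coupled receptor, had a fold of 30.95 at chromosome 6, 68764210 to 68764647, in a gene that held 50 wild-type and 26 knockout peaks. DEDD followed at 28.2 on chromosome 1, 161131891 to 161132157. NBPF20 had 27.96, in a family of near-identical copies that makes its position uncertain, and RAPGEF4 27.8. The next were KPNA5, SEPTIN7, THUMPD3, SLC25A53, BMPR2 and HIVEP2, with folds from 26.7 down to 24.3. All 10 of these genes also carried at least 1 knockout peak elsewhere in the gene.

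Among shared peaks in the body of exactly 1 gene the highest wild-type fold was 39.5, in PCMTD1 at chromosome 8, 51820422 to 51820785. DMXL1 followed with 35.8 at chromosome 5, 119117371 to 119117737, and PARD3, a cell polarity gene, with 35.4 at chromosome 10, 34317166 to 34317516. ANXA8, whose near-identical copies leave its reads uncertain, had 33.8, and PARP8, MAP7D3, TOP1, CLYBL, PBDC1 and EED ranged from 32.1 to 27.7. TOP1 encodes DNA topoisomerase I, and EED is a subunit of the Polycomb repressive complex that methylates histone H3.

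Of the peaks in the knockout list alone and in the body of exactly 1 gene, MARK1 had the highest fold, 27.6, at chromosome 1, 220636363 to 220636750. SUV39H2, a histone H3K9 methyltransferase, had 27.5 at chromosome 10, 14896844 to 14897162, and held 0 wild-type and 2 knockout peaks. The chromatin remodeller gene CHD2 had 27.1 at chromosome 15, 93002035 to 93002403. ITGA8, ANKRD18B, TDG, CDK11B, CCDC91, ZNF70 and ELOVL4 followed, from 25.8 to 22.6. ANKRD18B and CDK11B have close copies in the genome and are uncertain for that reason.

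Fold enrichment hardly separated lost from kept wild-type peaks. The median fold was 7.30 (quartiles 6.05 and 8.82) in the 23137 lost peaks and 7.24 (5.12 and 9.70) in the 5947 kept ones, a difference of 0.065 with a 2-sided permutation p = 0.219. Kept peaks were spread wider at both ends. The kept share was 35.9% in the 10% of wild-type peaks with the lowest fold, 12.5% in the fourth such group and 31.4% in the highest. The direction turned among the 50% of wild-type peaks with the highest fold, where lost minus kept fold was −0.934 against the whole knockout list (p = 1e-05, the smallest that 100000 permutations can give), a comparison added after seeing the data. With the knockout list limited in the same way, so that partners of lower fold no longer counted, it was −0.998 (permutation p = 1e-05). It also turned with −log10 q in place of fold, with medians of 8.91 in lost and 13.8 in kept peaks.

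Gene ends held few peaks of either kind. In wild type 3.11% of lost and 3.16% of kept peaks lay within 500 bp of a 5′ gene end (Fisher's exact test p = 0.835), and 3.07% and 2.96% within 500 bp of a 3′ end (p = 0.673). Over 20 shuffles, shuffled peaks gave means of 1.996% and 1.98%, with maxima of 2.15% at either end. Each of these wild-type shares was above those maxima. In the knockout 2.58% of unshared and 3.10% of shared peaks lay near a 5′ end (Fisher's exact p = 0.0339). That difference of −0.521 points was larger with a 1000-bp window (−1.09, exact p = 0.000561) and with reciprocal overlap (−0.738, p = 0.00506). With a 200-bp window the call was lost but not the direction (1.56% of unshared and 1.84% of shared peaks, exact p = 0.156). With equal numbers of strongest peaks the difference was −0.0855 points (exact p = 0.756), and it turned among the 50% of peaks with the highest fold in each list (p = 0.405). Near 3′ ends the knockout shares were 2.66% and 2.88% (exact p = 0.357).

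Protein-coding gene bodies held 77.9% of wild-type and 76.1% of knockout peaks. Shared peaks lay in them more often than unshared ones, at 81.2% against 77.1% in wild type (Fisher's exact test p = 4.29e-12) and 81.3% against 74.4% in the knockout (p = 6.77e-28). Peaks were found in 6185 genes in both lists, in 3655 in wild type alone and in 2362 in the knockout alone. Protein-coding genes made up 5337, 2606 and 1649 of these, and long noncoding RNA genes 848, 1046 and 713. Wild-type-only status went with few peaks. It applied to 56.3% of genes with 1 wild-type peak, 34.5% with 2 and 1.62% of those with 11 or more.

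By gene, 3 of the 15 lists differed from other genes in the share without a knockout peak, which was 37.1% among other genes. Oxidative phosphorylation genes of the nucleus had no knockout peak in 19 of 29 genes with a wild-type peak (65.5%, adjusted p = 0.0459, Fisher's exact test). The 4 members with the highest wild-type fold, NDUFB2, SDHC, NDUFA10 and NDUFS4, did have knockout peaks, although that of NDUFB2 lay on the strand opposite to its wild-type peak, and NDUFB5, NDUFB3, SDHB and NDUFC1 were among those without. Ribosomal protein genes lacked one in 10 of 13 (76.9%, adjusted exact p = 0.0465), among them RPL26L1, RPS27A, RPS29 and RPS21, the last with its peak on the strand opposite to the gene. All 11 m6A reader and eraser genes with a wild-type peak also had a knockout peak on either strand (adjusted exact p = 0.0465), but the wild-type peak of IGF2BP1 lay on the minus strand and its knockout peak on the plus strand. When a knockout peak had to lie on the strand of a wild-type peak, a setting added after seeing the data, readers and erasers no longer passed (1 of 11 without, adjusted exact p = 0.151). Oxidative phosphorylation (20 of 29) and ribosomal protein genes (11 of 13) did, both with an adjusted exact p = 0.0131. Each of the 3 calls was lost when genes were compared within strata of 1, 2 and 3 or more wild-type peaks, with an adjusted permutation p = 0.332 for each. Peak number was matched only in part. Among all genes the share without a knockout peak was 14.5% at 3 to 5 wild-type peaks and 1.62% at 11 or more. The differences in share went from 28.5 to 19.3 points for oxidative phosphorylation genes (unadjusted permutation p = 0.0303), from 39.8 to 25.7 for ribosomal protein genes (p = 0.0868) and from −37.2 to −25.4 for readers and erasers (permutation p = 0.0505). With equal numbers of strongest peaks, oxidative phosphorylation genes alone passed (adjusted exact p = 0.0120).

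The reader and eraser genes with peaks in both lists, strand not considered, were FMR1, FTO, HNRNPC, IGF2BP1, IGF2BP2, IGF2BP3, PRRC2A, YTHDC1, YTHDC2, YTHDF2 and YTHDF3. FTO, an m6A demethylase, held 12 wild-type and 9 knockout peaks, of which 4 were shared. YTHDF1, a cytoplasmic m6A reader, had 0 wild-type and 2 knockout peaks. Of 9 m6A writer genes with a wild-type peak, METTL3 alone had no knockout peak. ZC3H13, a writer subunit, held 10 and 7 peaks with 5 shared, WTAP 3 and 3 with 2 shared, and VIRMA 3 and 3 with 1 shared. RBM15 held 2 and 4 with 2 shared, and METTL14, METTL16, CBLL1 and RBM15B had 1 knockout peak each. The writer list did not pass the test (1 of 9, adjusted exact p = 0.359).

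Histone acetyltransferases and their partners had no knockout peak in 6 of 21 genes (28.6%, adjusted exact p = 0.685), namely ING4, ING5, KAT2B, KAT5, TADA3 and TRRAP. KAT6A held 9 wild-type and 11 knockout peaks with 6 shared, KAT6B 11 and 6 with 2 shared, KANSL1 11 and 5 with 3 shared, and CREBBP 8 and 6 with 2 shared. EP300 held 4 and 4 with 2 shared. Both lists also held peaks in BRPF3, EP400, EPC1, EPC2, HAT1, KAT7, MSL1, MSL2, TADA2A and TADA2B, while BRPF1 and KAT8 had knockout peaks alone. Histone deacetylases and their corepressors lacked a knockout peak in 6 of 16 genes (adjusted exact p = 1). Histone methylation enzymes lacked one in 4 of 26 (15.4%, adjusted exact p = 0.0900), the 4 being KDM3B, KDM5B, SETDB1 and SETDB2. SETDB1 encodes an H3K9 methyltransferase.

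In the fixed list of chromatin-retained and other long noncoding RNAs, the genes with a wild-type peak in their bounds all had a knockout peak (9 of 9, strand not considered, adjusted exact p = 0.0939). Of all 1894 long noncoding RNA genes with a wild-type peak, 1046 had no knockout peak. FTX held 6 and 11 peaks with 3 shared, JPX 6 and 8 with 3 shared, KCNQ1OT1 7 and 6 with 1 shared and TUG1 3 and 3 with 2 shared. MALAT1 held 3 and 1, PVT1 3 and 4 and NORAD 1 and 1 with 1 shared in each, and LINC-PINT 2 and 2 with none shared. The bounds of SNHG14 held 3 and 4 with 2 shared, all on the minus strand, whereas SNHG14 is transcribed from the plus strand and UBE3A, which it overlaps, from the minus strand. DANCR had a peak in the knockout alone. FTX and JPX overlap in part, so some of their peaks count for both.

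The remaining lists did not pass. Early-response genes lacked a knockout peak in 4 of 9 (FOSL2, ID2, KLF10 and MYC, adjusted exact p = 0.918), ZNF-named zinc finger genes in 93 of 271 (34.3%, 0.551) and splicing factors in 5 of 16 (0.920). Mitochondrially encoded genes lacked one in 3 of 5 (CYTB, ND4 and ND4L, 0.551), where ND4 and ND4L share 1 peak so that the 3 genes rest on 2 peaks, and replication-dependent histone genes in 1 of 2 (H2BC18, 1). The carriers of METTL3-independent methylation lacked one in 3 of 3 (0.128), which were the U6 snRNA copies RNU6-7, RNU6-8 and RNU6-9, whose near-identical copies leave their reads uncertain. Genes of other cell types lacked one in 3 of 5 (0.551). Among them the bounds of TTN held 8 wild-type and 0 knockout peaks. All 8 lay on the plus strand, opposite to TTN, and 7 lay in the noncoding LOC124906100 within those bounds.

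Counted by peak, a way added after seeing the data, 7 lists differed from other gene peaks. The unshared share was lower in ZNF-named genes (70.6% against 79.1%, adjusted exact p = 2.96e-05), readers and erasers (56.8%), writers (56.0%), splicing factors (54.5%), long noncoding RNAs (57.6%) and histone methylation enzymes (67.9%). It was higher in oxidative phosphorylation genes (95.3%, adjusted exact p = 0.0151). Ribosomal protein genes, called by gene, did not pass by peak, with 81.25% of 16 peaks unshared against 78.9%. Against gene peaks with a like number of IP reads 0 lists passed. The difference of ribosomal protein genes went from 2.35 to 13.1 points. The difference of oxidative phosphorylation genes went from 16.5 to 13.2 points (permutation p = 0.0191, adjusted 0.175) and that of ZNF-named genes from −8.46 to −3.73 (permutation p = 0.0234, adjusted 0.175).

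A test of each gene's number of peaks, added after seeing the data, called 4 of 12202 genes. Each had nearly all of its peaks in 1 list, which is the imbalance that the test selects for. LINGO2, which encodes a transmembrane protein with leucine-rich repeats, had 0 wild-type and 35 knockout peaks (adjusted p = 9.82e-09, Fisher's exact test with Benjamini-Hochberg adjustment). DLGAP1, a gene of the postsynaptic scaffold, had 0 and 18 (adjusted exact p = 0.00246). TENM1, a teneurin gene on chromosome X, had 42 and 1 (adjusted exact p = 1.54e-06), and the noncoding LOC105371657 on chromosome 1 had 20 and 0 (adjusted p = 0.0280). Unadjusted, 154 genes had p under 0.05. Among the 50% of peaks with the highest fold LINGO2 and TENM1 remained past the threshold. With only peaks of at least 20 reads LINGO2, TENM1 and MIR3171HG passed, while DLGAP1 and LOC105371657 did not. MIR3171HG, with 6 wild-type and 20 knockout peaks in all, had not passed with all peaks. The cut is on unscaled reads, so it is not equally strict for both lists.

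**Figure D2:**
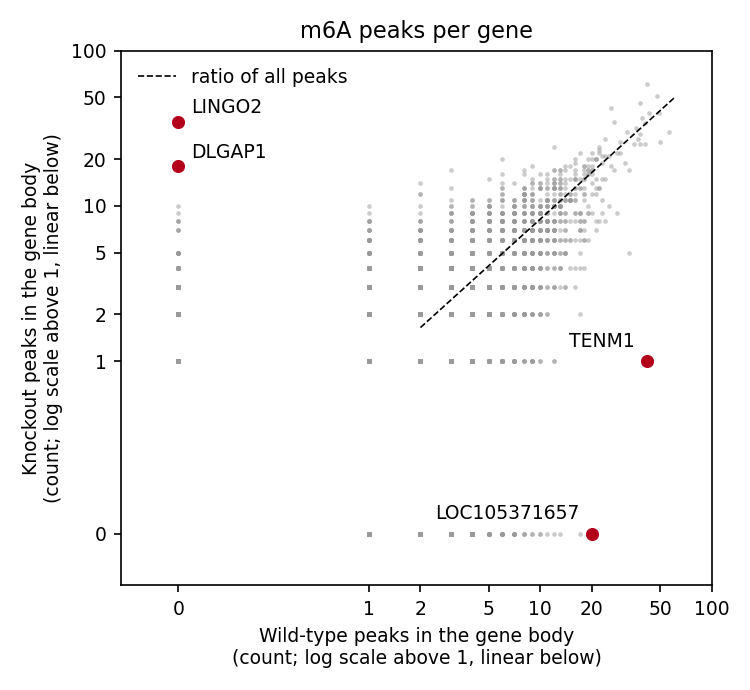
Number of knockout peaks (vertical axis) against wild-type peaks (horizontal axis) for each gene body with a peak, on axes that are logarithmic above 1 and linear below, with the ratio of all peaks as a dashed line. LINGO2 (0 and 35), DLGAP1 (0 and 18), TENM1 (42 and 1) and LOC105371657 (20 and 0), each given as wild-type and knockout peaks, are the genes past the test.

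The peaks of these genes were spread along the gene bodies and lay on 1 strand. In LINGO2, on chromosome 9 from 27937617 to 29213601, 33 of 35 peaks were on the minus strand and spanned 1190 kb. In TENM1, from 124375903 to 125204312, all 42 wild-type peaks were on the minus strand and spanned 791 kb, while the knockout peak was on the plus strand. The 18 DLGAP1 peaks were all on the minus strand, and 19 of the 20 in LOC105371657 on the plus strand. Median folds were 7.18 in LINGO2, 7.21 in TENM1, 7.12 in DLGAP1 and 7.61 in LOC105371657. The next genes, ULK4 with 33 and 5 peaks and PTPRD with 17 and 0, did not pass (adjusted exact p = 0.121 and 0.134). Over the 15 fixed lists 0 genes passed Fisher's exact test when adjusted over all genes and TTN alone passed when adjusted over the list alone (0.0496), on peaks opposite to its own strand, with 7 of 543 members under an unadjusted p of 0.05.

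**Figure D3:**
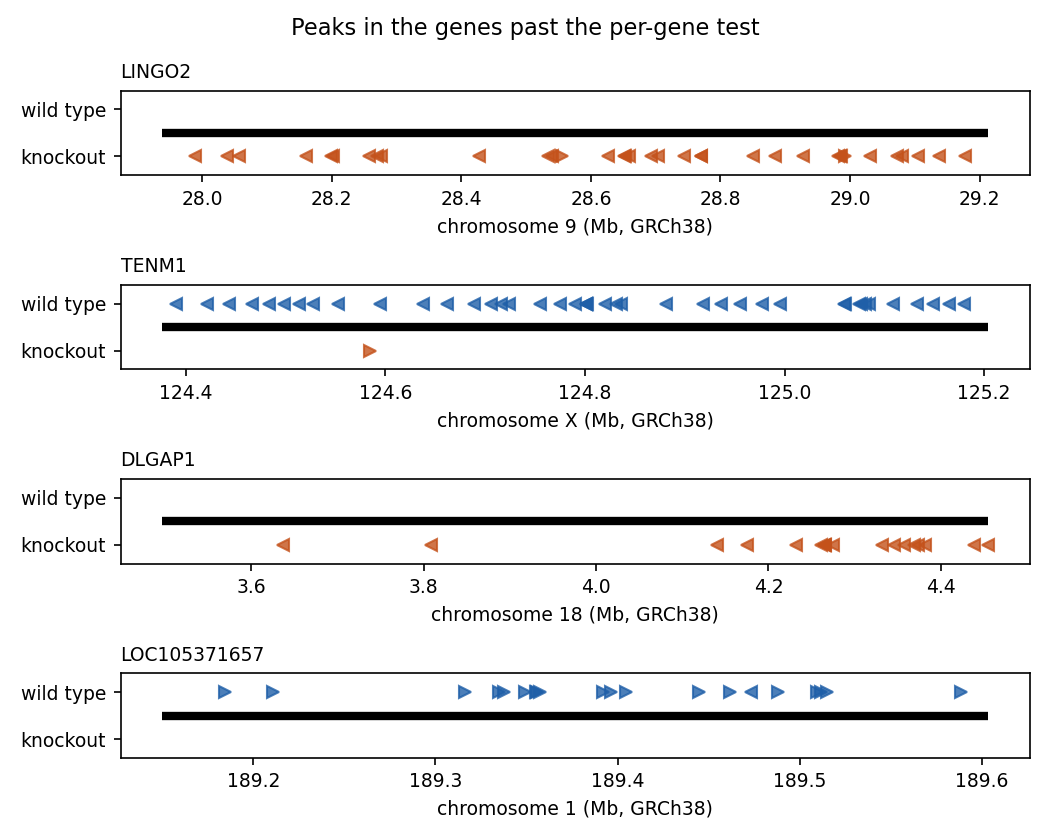
Positions of wild-type (upper) and knockout (lower) peaks along the gene bodies (black bars) of LINGO2, TENM1, DLGAP1 and LOC105371657, in Mb of GRCh38. Triangles point right for the plus strand and left for the minus strand, and 35 knockout peaks of LINGO2 and 42 wild-type peaks of TENM1 run along most of each gene.

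Chromosomes differed in their share of the knockout list, in a test also added after seeing the data. Chromosome 14 held 930 wild-type and 997 knockout peaks, a share 1.30 times as large in the knockout (adjusted p = 8.07e-08, Fisher's exact test). Chromosomes 5 (1.20), 19 (1.21) and 1 (1.09) were also higher, and chromosomes 2 (0.922), 13 (0.881) and 22 (0.840) lower. Without the 10 genes of each chromosome with the most peaks in both lists together, 6 of these 7 chromosomes remained past the threshold in the same direction. Chromosome 22 did not (ratio 0.834, adjusted exact p = 0.0660). Chromosome 16 passed only without these genes (ratio 0.864, adjusted exact p = 0.0321, against 0.921 and 0.213 with all genes). Along chromosome 14 the ratio was 1.33, 1.35, 1.41 and 1.14 in 4 consecutive parts with near-equal numbers of peaks, and the last did not pass (exact p = 0.168). At 211 shared peaks on chromosome 14 the local input was higher in the knockout by a median log2 of 0.61 (95% bootstrap interval 0.46 to 0.72). Over all 5393 shared pairs it was −0.08. Across the 23 chromosomes the peak ratio and the input ratio had Pearson r = 0.534 (permutation p = 0.00972) and Spearman rho = 0.442 (p = 0.0364). Without chromosomes 14 and 19 these were 0.312 (permutation p = 0.170) and 0.364 (p = 0.107). Without chromosome 14 alone they were 0.290 (permutation p = 0.192) and 0.362 (p = 0.0991), and without chromosome 19 alone 0.581 (permutation p = 0.00675) and 0.447 (p = 0.0385), so neither passed the threshold without chromosome 14. It was the 1 relation of its kind computed.

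**Figure D4:**
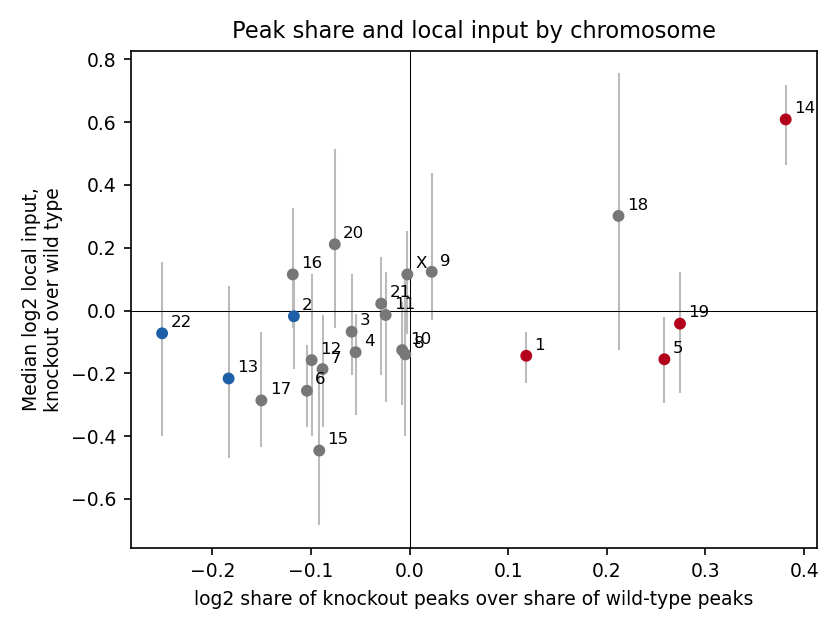
Median log2 ratio of knockout over wild-type local input at shared peaks, with 95% bootstrap intervals (vertical axis), against the log2 ratio of the knockout to the wild-type share of peaks (horizontal axis), for 23 chromosomes. Red and blue points passed the test as higher and lower in the knockout, and chromosome 14 stands highest on both axes, at an input ratio of 0.61.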

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

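Tests chosen after the results were seen are those on the 10% of peaks with the highest −log10 q, −log10 q in place of fold, high wild-type folds against the whole knockout list, the lists counted by peak (plain or by read support) or by strand, and all settings of the per-gene test. No paired analysis was possible because the lists carry no replicate, and for the same reason none was left out. The shares over exons, motif density and assignment or shuffling by exons were not run for want of exons and sequence here. The cause was not tested for any change below unless stated.

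Peaks numbered 15131 in wild type and 11380 in the knockout above the pooled median fold, or 75.2 per 100. The unshared share in wild type and knockout was 83.0% and 79.3% with reciprocal overlap, 76.6% and 71.6% within 500 bp, and 46.5% and 41.4% in the top 10% by −log10 q against the whole other list. With both lists limited, so that weaker partners no longer count, it was 87.4% and 85.0% among the 50% with the highest fold and 81.9% and 81.9% with equal numbers. Lost minus kept fold was −0.0704 with reciprocal overlap, −0.998 among the highest folds, −0.934 when the wild-type list alone was so limited, −0.703 with equal numbers, and −4.93 in −log10 q. The 5′-end difference in wild type turned to 0.484 points among the highest folds and 0.155 at 200 bp. In the knockout it was 0.352 among the highest folds, −0.0855 with equal numbers and −0.274 at 200 bp. Genes with peaks in both lists fell to 3446 among the highest folds, where fewer peaks enter, and the per-gene test called 2 genes.

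Lists past the threshold numbered 3 by gene, 1 with equal numbers, 0 within strata of peak number, 2 with a knockout peak required on the strand of a wild-type peak, 7 by peak and 0 by peak at like read support. Directions that turned, in points of unshared share against the comparison, were acetyltransferases 2.46, early-response −4.58 and replication-dependent histones −6.29 within strata. By strand deacetylases turned to −1.73. By peak they were deacetylases −11.5, early-response −12.2, and replication-dependent histones and mitochondrial genes both −28.9. At like read support they were acetyltransferases 3.59, deacetylases −11.6, early-response −3.13, histones −10.3 and splicing factors 4.95. None of these passed. In 21 further settings of the leading values and 46 of single lists, direction and side of the threshold held, or the value stayed in its counting interval or within 1.5 times. Single lists lost a call in 10 settings and gained one in 5. At low read support, wild-type summits of up to 15 reads were shared in 5.53%. Loss of a site there cannot be told apart from too few reads.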

Other observations

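Tests chosen only after the results were seen are those on read support, on the depth of both libraries, on direct loss of METTL3 methylation, on the genes with the most peaks, on chromosome 14, on the other chromosomes and on the correlation without 1 chromosome.

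Outside the fixed lists, the genes nearest to the threshold of the per-gene test had most peaks in 1 list, which the test selects for. RTN1 had 0 wild-type and 10 knockout peaks, LRFN5 0 and 9, B3GALT1 3 and 17 and KCTD8 2 and 14, while KCNT2 had 13 and 0. None passed after adjustment, and the adjusted p of RTN1, B3GALT1 and KCNT2 was 0.595. They were chosen for mention after their values were seen.

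Most wild-type peaks had no knockout partner, although the lists met far above chance. Uniform random placement within the same merged gene bodies is argued against by 21.1% of wild-type gene-body peaks being shared, against at most 1.63% in relocations. The relocations took no account of exons or read coverage, so random placement within the covered parts of genes was not tested. Too few reads per peak as the whole cause stays open. Above 100 reads 69.3% were shared, and the share that replicates within a genotype would reach is not known here. The knockout list gave 69.9% above 100 reads, but its reads are not on the same scale. A knockout IP library with fewer reads is argued against by a recovered depth of at least 1.17 times wild type. In the fold, however, knockout IP reads were scaled by 0.479 and 0.438, against 0.607 and 0.572 in wild type. The extra reads were thus weighted down, and a higher effective IP depth in the knockout call is not shown. A shallower knockout input, at 0.918 of wild type, stays open for the lower number of peaks. It cannot be told apart from loss of METTL3 methylation. Counted reads include duplicates.

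The genes with peaks almost only in 1 list were LINGO2, DLGAP1, TENM1 and LOC105371657. Stray DNA or unstranded background is argued against by 96.6% of their peaks in both lists (112 of 116) lying on the gene's main strand. A transcript present in the line that has the peaks met its bound, with 84.3% of the peaks where local input exceeded the library floor. The genes differed in this. It held for 41 of 42 peaks in TENM1 and 19 of 20 in LOC105371657, against 84.0% of all wild-type peaks. In LINGO2 it held for 27 of 35 and in DLGAP1 for 10 of 18, against 82.2% of all knockout peaks. As most peaks of either list exceed the floor, the test adds little. Direct loss of METTL3 methylation would remove peaks, whereas all 53 peaks of LINGO2 and DLGAP1 were in the knockout list. These 2 genes were picked for that imbalance, so the count restates the pattern and decides nothing on its own. Direct loss was not tested and stays open for TENM1 and LOC105371657. A candidate explanation is that transcription of these long genes differs between the cell lines used, which input read counts, not used here, could test.

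Chromosomes differed in their peak ratio. A few genes with many peaks are argued against as the whole cause, since 6 of the 7 chromosomes passed without the 10 genes of each with the most peaks. RNA level in the input met its bound across chromosomes (rho = 0.442). That bound was set before this correlation was seen, but after the data had been examined. By rho the correlation passed the threshold neither without chromosomes 14 and 19 (0.364) nor without chromosome 14 alone (0.362, permutation p = 0.0991). Nor did rho pass without any 1 of 8 others. By r it passed without each of those 8, where the highest permutation p was 0.0292, without chromosome 18 (r = 0.481). As neither coefficient passed without chromosome 14, the relation is weak. On chromosome 14 a raised input level, at a median log2 of 0.61, may account for the higher share of peaks, and a gain of the chromosome in the knockout line would be 1 source of it, which was not tested. For chromosomes 1, 5 and 19, with a pooled median log2 of −0.14, an input raised by as much as the peak ratio is argued against. A smaller rise above the median of all pairs, −0.075, stays open on each. The 95% bootstrap intervals reached from −0.230 to −0.069 on chromosome 1 and from −0.293 to −0.021 on chromosome 5. On chromosome 19 (median −0.04) the interval was −0.26 to 0.12.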
